A study of Mus musculus with 8 samples.

How the data were processed

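The samples were mouse (C57BL/6) intraepithelial lymphocytes, the immune cells that sit between the epithelial cells of the gut lining. Per the labels' protocols they had been sorted on the leukocyte surface protein CD45 and kept for 24 h in culture medium with 10% serum, either with recombinant osteopontin at 2 µg/ml (4 libraries) or without it (4 libraries, called null). Per the labels, total RNA was taken with a micro-scale column kit and turned into stranded Illumina libraries. The libraries of both groups carry the names 1, 2, A and B. The labels do not say whether the libraries came from separate animals or cultures, so p-values measure the spread between these libraries, which may be partly technical.

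Salmon is named in the submitters' processing notes; its version, the transcript release and the genome build are not given in the sources used here. The authors deposited 1 transcript table per library, with estimated counts (reads assigned to each transcript, not necessarily whole), TPM (transcript abundance corrected for length and scaled to the same sum in every library) and an effective length. The deposited effective length (in bases, per the file headers) was used only as an offset in 1 alternative, and the deposited TPM values were not used in any test. All tables held the same 133618 transcripts of 52661 genes, identified by gene and transcript identifiers in each row. Estimated counts were summed per gene over all transcripts and rounded to whole numbers. Library totals ranged from 49108969 to 71399847 estimated reads. A count of 3 reads corresponded to 0.0420 to 0.0611 CPM (a gene's reads over the library total, scaled to a fixed library size), which is the floor that counting error alone sets. Salmon divides reads shared by near-identical transcripts, so levels of close relatives such as Hspa1a and Hspa1b, the Bcl2a1 genes and immunoglobulin segments are uncertain individually.

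Osteopontin and null libraries were compared with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, two-sided, group as the only term), after filterByExpr with a minimum count of 10 and TMM scaling. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 18631 tested genes were called. Standard errors are the fold change divided by the square root of F, and 95% intervals use the moderated degrees of freedom. Levels of named genes are CPM on TMM-scaled totals, and levels of marker sums and of genes named outside the rule are CPM on plain totals. All fold changes are osteopontin over null on the log2 scale. The 30 fixed gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and, beside it, a correlation estimated per list. The rotation test fry was run as well. Only lists with at least 5 tested genes entered. Single values per library were compared with exact permutation tests over all 70 arrangements of 4 against 4 libraries, two-sided, with Benjamini-Hochberg adjustment over 17 measures.

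The tests, the lists, the alternatives and the rule for naming genes were written before the data were examined. The rule left out predicted genes, clone-named genes, pseudogenes and antigen receptor segments. It took, per direction, up to 12 called genes with the largest change whose groups did not overlap and whose mean was at least 5 CPM in the higher group. Where fewer than 5 qualified, it took the 8 with the smallest p among genes with a mean of at least 5 CPM, named as not passing. From each list it took up to 4 called members, or the member with the smallest p, and it always took 17 genes of osteopontin binding, survival and lymphocyte identity. This gave 58 genes, of which 57 were tested, and the results of 2 of them are not reported here. Genes named outside the rule are identified as such. The marker sums (fibroblast, endothelial, enterocyte, B cell, plasma cell, inducible stress and T cell receptor constant genes) were put together after the data were seen.

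The lists covered T cell and intraepithelial lymphocyte identity, cytotoxic effectors, NK and innate lymphoid markers, regulatory T cell genes, Th1 and interferon-gamma genes, Th2 and Th17 genes, T cell activation, osteopontin and its receptors, anti-apoptotic genes, pro-apoptotic genes, p53 targets, NF-kB targets, STAT5 targets, interferon-stimulated genes, TGF-beta and residency genes, cell cycle, glycolysis and hypoxia, cholesterol and lipid synthesis, oxidative phosphorylation, the unfolded protein and integrated stress response, heat shock and immediate-early genes, endotoxin-responsive myeloid genes, markers of enterocytes, of goblet, Paneth, tuft and endocrine cells, of B and plasma cells, of macrophages and dendritic cells, of neutrophils, mast cells and eosinophils and of stromal, endothelial and red cells, mitochondrially encoded transcripts and cytosolic ribosomal proteins.

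The alternatives were the replicate name as a block, the digit or letter naming as a covariate, 3 other scalings, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter of at least 5 CPM in at least 4 libraries, an effective-length offset, protein-coding genes only, each library left out in turn, adjusted p thresholds of 0.01 and 0.10, a test against a 1.5-fold change, and the other list tests. Leaving out both B libraries, or null libraries 1 and A, was added after the data were seen. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 37.1 to 93.4), so none was treated as a library deposited in duplicate. This does not show that they came from separate cultures.

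The calls were tested on simulated data for this comparison: counts for the 18631 genes from the measured means, dispersions and library sizes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold, all drawn from genes with a mean of at least 5 CPM. The edgeR test recovered 38.8% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 5.96% of its calls false. With no gene changed it called 0. DESeq2 on the same counts recovered 41.8%, 80.6% and 100% at those sizes, with 29.2% of its calls false, and voom recovered 35.8%, 73.1% and 93.9%, with 2.17% false. Shifting the heat shock list 1.3-fold gave an adjusted p of 2.19e-14 with the preset and 0.00325 with the estimated correlation, and called 0 other lists. Each gene was drawn independently, so the simulated lists held no correlation between genes. This run therefore does not show how often lists are called falsely in the real data. Gene positions are those of GENCODE M21 on GRCm38, matched by gene identifier for all 73 genes looked up. R 4.3.3 and Python 3.11.15 were used.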

Results

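Transcript levels were measured by RNA sequencing in CD45-sorted mouse intraepithelial lymphocytes kept for 24 h with or without recombinant osteopontin, a secreted phosphoprotein that binds CD44 and several integrins. There were 4 osteopontin and 4 null libraries. The osteopontin libraries named 1, 2, A and B held 71292125, 68199331, 58086036 and 49108969 estimated reads, and the null libraries of those names held 57492806, 64330529, 71399847 and 65554396. At this depth between 20225 and 23812 genes had at least 1 read. The question was how the expression profile of these cells differed with osteopontin.

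Transcripts of intraepithelial T cells were abundant in both groups. Ptprc, which encodes CD45, stood at 2096 ± 50.8 CPM with osteopontin and 1982 ± 74.3 without (SD, n = 4 each). Itgae, the CD103 integrin chain that holds these cells to the epithelium, stood at 1225 ± 54.0 and 1128 ± 53.9 CPM, and Cd8a at 964.1 ± 51.6 and 919.5 ± 66.2 CPM. Constant-region transcripts of the alpha-beta T cell receptor summed to 1131 ± 48.2 and 1115 ± 52.0 CPM, and those of the gamma-delta receptor to 888.2 ± 52.6 and 866.1 ± 81.6 CPM. Both receptor sums differed by less than the spread between libraries (exact permutation p = 0.714 and 0.629, two-sided, adjusted p = 0.759 and 0.745).

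No gene passed the test between osteopontin and null libraries. With edgeR's quasi-likelihood test, 0 of 18631 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.470. An unadjusted p under 0.05 was found for 732 genes, 344 with a higher and 388 with a lower fitted level, where 931.6 would be met by chance. Groups did not overlap for 3.47% of the genes, where chance gives 2.86%. Changes of large size were excluded for most genes: among 10616 genes with a mean of at least 5 CPM, the 95% interval lay within a 2-fold change for 9949 (93.7%) and within a 1.5-fold change for 8074 (76.1%). DESeq2 called 21 genes higher and 59 lower, and limma voom called 0 and 1. The lower DESeq2 calls included collagen genes (Col6a1, Col6a2, Col6a3 and Col14a1) and the stromal markers Dcn and Pdgfra. Dcn stood at 56.3 and 57.1 CPM in null libraries 1 and A but at 3.40 and 0.397 CPM in null libraries 2 and B. With osteopontin it stood at 0.155 to 1.10 CPM. Such calls can therefore reflect stromal RNA in single null libraries. Without osteopontin library B, edgeR called 2 higher and 35 lower. Leaving out null library 1 gave 1 higher, and leaving out osteopontin library 2 or null library 2 gave 1 lower each.

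None of the genes nearest to the threshold passed it. Ubn2 (chromosome 6, 38433950 to 38524825 on GRCm38, as all positions here are whole-gene spans on that build), a histone chaperone subunit, stood at 224.6 ± 11.0 CPM with osteopontin and 169.6 ± 15.8 without, a log2 fold change of 0.41 (SE 0.07, edgeR adjusted p = 0.470), and all 4 osteopontin libraries lay above all 4 null libraries. Clec2d (chromosome 6, 129180615 to 129186534), a lectin-like ligand of an inhibitory NK cell receptor, stood at 164.0 ± 6.10 and 207.6 ± 8.63 CPM, a log2 fold change of -0.34 (SE 0.06, edgeR adjusted p = 0.470), also without overlap. The next genes with a higher fitted level were Zfp871 (0.31), Zfp652 (0.25), Phc3 (0.23), Kmt2d (0.27), Taok1 (0.26), Gbp8 (0.28) and Fnbp1 (0.20), as log2 fold changes. Those with a lower one were Zfp36 (-0.35), Nid1 (-1.75), Tsc22d3 (-0.55), Anxa2 (-0.38), Hspa5 (-0.25) and Eloa (-0.29). All of these 13 genes had an edgeR adjusted p of 1.00 when rounded. Among these genes DESeq2 called Ubn2 (adjusted p = 5.28e-04), Zfp871, Zfp652, Phc3 and Fnbp1 higher and Clec2d (adjusted p = 1.74e-04), Zfp36, Nid1 and Hspa5 lower. Without osteopontin library B, edgeR called Ubn2 (adjusted p = 0.0460), and without both B libraries it called Nid1 lower (adjusted p = 0.0140). Nid1 stood at 21.2 and 20.6 CPM in null libraries 1 and A and at 8.22 and 4.61 CPM in null libraries 2 and B. With osteopontin it stood at 3.03 to 4.51 CPM.

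No gene of osteopontin binding passed the test. Spp1 itself (chromosome 5, 104435118 to 104441050) was close to the counting floor, at 0.126 ± 0.0986 CPM with osteopontin and 0.0943 ± 0.126 without, and was not tested. Its receptor Cd44 stood at 79.8 ± 11.4 and 89.4 ± 6.66 CPM (log2 fold change -0.16, 95% interval -0.38 to 0.06). The integrin chains Itga4 (0.11, -0.03 to 0.25), Itgav (0.12, -0.06 to 0.29), Itgb1 (-0.11, -0.32 to 0.09) and Itgb3 (-0.10, -0.40 to 0.21) had intervals that included 0. Itga9 (-0.67, -2.32 to 0.98) was near 1 CPM and poorly determined. Of the 9 tested members of this list 4 had a higher and 5 a lower fitted level, 0 were called over all genes or adjusted over the list alone, and the member with the smallest p was Itgb5 at 1.85 ± 1.14 and 4.38 ± 2.33 CPM. The median of the list was -0.10 (camera adjusted p = 0.567). The fold change of Itgb3 turned to 0.056 without null libraries 1 and A.

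**Figure D1:**
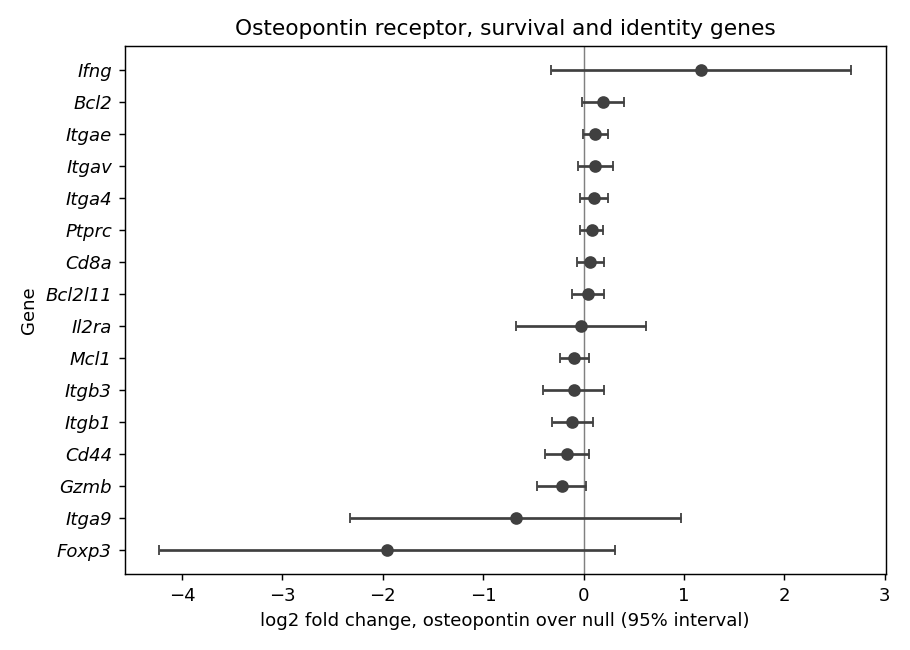
Log2 fold change of osteopontin over null (x axis) with its 95% interval for 16 genes of osteopontin binding, survival and lymphocyte identity fixed before the data were examined (y axis), n = 4 libraries per group. Every interval includes 0, from -4.23 to 0.32 for Foxp3 and from -0.33 to 2.67 for Ifng.

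Survival genes did not pass the test either. The anti-apoptotic Bcl2 stood at 64.5 ± 6.37 and 56.3 ± 4.85 CPM (log2 fold change 0.20, 95% interval -0.02 to 0.41) and Mcl1 at 447.1 ± 34.4 and 476.4 ± 27.0 CPM (-0.09, -0.23 to 0.05). The pro-apoptotic Bcl2l11 stood at 147.4 ± 10.7 and 142.9 ± 9.35 CPM (0.04, -0.11 to 0.20), and its fold change turned to -0.024 without null libraries 1 and A. Among 19 anti-apoptotic genes 10 had a higher and 9 a lower fitted level, with Birc6 nearest the threshold (0.17). Among 27 pro-apoptotic genes 13 were higher and 14 lower, with Bbc3 nearest (0.20), and 0 of either list were called over all genes or adjusted over the list alone. The p53 targets (median log2 fold change -0.01, Btg2 nearest at -0.24), NF-kB targets (0.00, Tnfaip3 at 0.23) and STAT5 targets (-0.02, Bcl6 at -0.22) also had 0 called genes over all genes or adjusted over the list alone. The mean was -0.01 for the anti-apoptotic genes, with a median of 0.01, and -0.06 for the NF-kB targets, and camera gave both as lower. Camera adjusted p for these 5 lists ranged from 0.354 to 0.898.

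Lymphocyte programs showed no called gene. Granzyme B (Gzmb) stood at 77.5 ± 9.34 and 90.1 ± 14.9 CPM, and perforin (Prf1) at 13.0 ± 2.46 and 17.8 ± 4.24 CPM (log2 fold change -0.45, SE 0.21, edgeR adjusted p = 1.00). Ifng was low, at 2.99 ± 0.419 and 1.33 ± 0.939 CPM, and Foxp3 at 0.676 ± 0.775 and 2.64 ± 1.07 CPM. For Ifng the osteopontin libraries all lay above the null libraries, a separation met by 3.47% of all tested genes in either direction. Foxp3 stood at 1.57 and 1.07 CPM in osteopontin libraries 1 and 2 but at 0.0171 and 0.0406 CPM, under the counting floor, in A and B. Il2ra stood at 8.27 ± 3.11 and 8.41 ± 2.64 CPM, and its fold change of -0.03 turned to 0.07 without osteopontin library 1, 0.12 without osteopontin library 2 and 0.18 without null library A. The median log2 fold change was -0.02 for T and intraepithelial identity (27 genes, Cd244 nearest), -0.06 for cytotoxic effectors (16), -0.14 for NK and innate lymphoid markers (18, Il1rl1 nearest) and -0.04 for regulatory T cell genes (19, Ikzf2 nearest). It was 0.04 for Th1 and interferon-gamma genes (16) and -0.02 for Th2 and Th17 genes (11). Camera called none of these 6 lists with the preset correlation (adjusted p from 0.0953 to 0.898), and 0 members were called over all genes or adjusted over the list alone. Cytotoxic effectors were called lower without osteopontin library 2 (0.0286), without osteopontin library A (0.0402) and without null libraries 1 and A (0.0454), against an adjusted p = 0.617 with an estimated correlation over all 8 libraries.

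Camera with the preset correlation called 7 of the 30 lists, all lower with osteopontin, and with an estimated correlation called 0. Mitochondrially encoded transcripts, a list of coding genes only, had a median log2 fold change of -0.40, with 12 of 13 members fitted lower. The preset adjusted p was 1.35e-12, and the adjusted p = 0.291 with an estimated correlation. Respiratory-chain gene mt-Cytb stood at 1349 ± 219.3 CPM with osteopontin and 2023 ± 330.4 without, and 5 members were lower adjusted over the list alone against 0 over all genes. The share of reads on mitochondrial coding genes was 1.44% ± 0.260 with osteopontin and 1.94% ± 0.245 without (exact permutation p = 0.0571, two-sided, adjusted p = 0.324). It was 1.46%, 1.49%, 1.71% and 1.08% in osteopontin libraries 1, 2, A and B, and 1.64%, 1.88%, 1.99% and 2.23% in the null libraries.

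Heat shock and immediate-early genes had a median of -0.30, with 21 of 24 fitted lower (preset adjusted p = 1.76e-11, and adjusted p = 0.0897 with an estimated correlation). Its members differed widely in fold change. The chaperones Hspa8, Hsp90aa1 and Dnajb1 had fold changes of -0.06, -0.09 and 0.01, while the rapidly induced Fos, Fosb, Hspa1a and Hspa1b had -2.19, -2.31, -1.58 and -1.60. These 7 genes and Atf3 were chosen after their values were seen. Fos (chromosome 12, 85473890 to 85477273) stood at 0.224, 0.425 and 0.103 CPM in osteopontin libraries 1, 2 and A, at 18.9 CPM in osteopontin library B, and at 29.5, 18.9, 25.5 and 15.1 CPM in the null libraries. Hspa1a likewise stood at 0.834, 0.277 and 0.594 CPM, then 30.7 CPM, against 13.8 to 36.6 CPM in the null libraries. Zfp36, which destabilises cytokine messages, was the member nearest the threshold, and 2 members, Zfp36 and Atf3, were lower adjusted over the list alone.

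Markers of stromal, endothelial and red cells, which a CD45 sort should remove, had a median of -1.04 with 14 of 16 fitted lower (preset adjusted p = 1.58e-04, and adjusted p = 0.442 with an estimated correlation). They differed between single libraries in both groups. Fibroblast transcripts summed to 290.2 and 151.4 CPM in null libraries 1 and A and to 9.90 and 6.28 CPM in null libraries 2 and B, against 6.63 to 24.3 CPM with osteopontin. Endothelial transcripts summed to 35.7 CPM in osteopontin library B, 36.3 in null library 2 and 34.7 in null library B, and to between 1.06 and 5.13 CPM in the other 5. Osteopontin libraries 1, 2 and A, with Fos under 1 CPM, had a fibroblast sum of at most 7.46 CPM and an endothelial sum of at most 5.13 CPM, and each of the other 5 libraries exceeded at least 1 of these values. Pdgfra, a fibroblast receptor, had the smallest p of the list, was called by DESeq2 (adjusted p = 0.00497) and stood at under 5 CPM in every library (log2 fold change -4.80, 95% interval -7.37 to -2.24). It was the 1 member lower adjusted over the list alone, and edgeR called it lower without both B libraries (adjusted p = 0.00724).

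**Figure D2:**
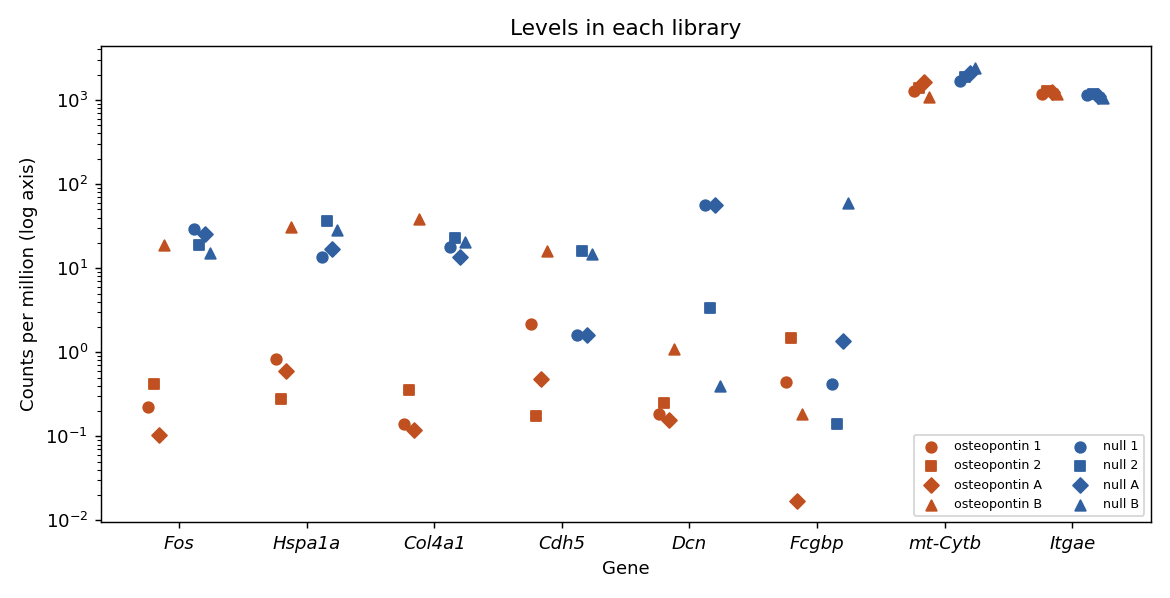
Level of 8 genes (x axis) in each library as CPM on a log axis (y axis), with osteopontin libraries in orange and null libraries in blue and the marker shape giving the library name. Fos lies between 0.103 and 0.425 CPM in osteopontin libraries 1, 2 and A and at 15.1 CPM or more in the other 5.

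B and plasma cell markers had a median of -0.34 with 18 of 20 fitted lower (preset adjusted p = 4.99e-05, and adjusted p = 0.563 with an estimated correlation). Summed B cell transcripts stood at 632.7 ± 245.7 CPM with osteopontin and 847.8 ± 112.4 without (exact permutation p = 0.200, two-sided, adjusted p = 0.673), with 316.6 CPM in osteopontin library B, and the list was not called without that library (camera adjusted p = 0.0520). The plasma cell transcripts Igha, Igkc and Jchain summed to 5798 ± 2330 and 5886 ± 2736 CPM. Ebf1 was the member nearest the threshold (-0.50).

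The unfolded protein and integrated stress response had a median of -0.14 with 19 of 24 fitted lower (preset adjusted p = 2.42e-04, and adjusted p = 0.0897 with an estimated correlation), and was the 1 list that fry called (adjusted p = 0.0236, and 0.148 with the replicate block). Hspa5 (chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, stood at 246.0 ± 16.2 CPM with osteopontin and 293.1 ± 16.9 without, lower in all 4 osteopontin libraries than in any null library. Adjusted over the list alone 2 members, Hspa5 and Atf3, were lower. Cholesterol and lipid synthesis had a median of -0.11 with 18 of 24 lower (preset adjusted p = 0.0110, and adjusted p = 0.617 with an estimated correlation), with Sqle nearest (-0.26). T cell activation had -0.13 with 20 of 25 lower (preset adjusted p = 0.0317, and adjusted p = 0.291 with an estimated correlation), with Tnfrsf18 nearest (-0.37). The estimated correlation was -0.00842 for the unfolded protein list and 0.00798 for T cell activation, both below the preset 0.01. Correlation between genes therefore does not account for the weaker results of these lists under the estimated setting. Without osteopontin library B the camera adjusted p was 0.128 for the cholesterol list and 0.0520 for T cell activation. The cholesterol call was also lost without osteopontin library 2 (0.0520), and the T cell activation call without osteopontin library 2 (0.09996), null library 1 (0.0518) or null library B (0.116). With voom both calls were lost (0.0960 and 0.0551), and with protein-coding genes only the T cell activation call was lost (0.0668).

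**Figure D3:**
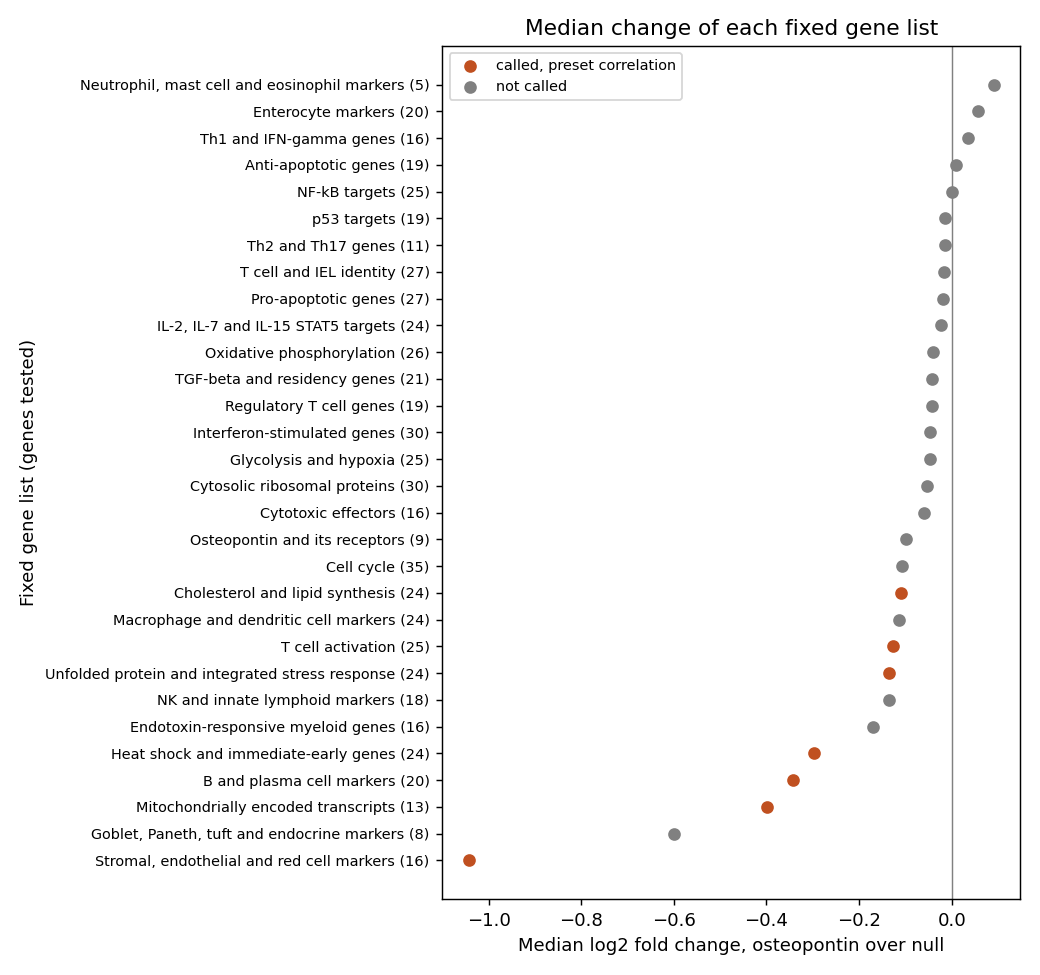
Median log2 fold change of osteopontin over null (x axis) for each of the 30 fixed gene lists with the number of genes tested (y axis). The 7 lists called by camera with the preset correlation are in orange and have medians from -1.04 to -0.11, and none is called with an estimated correlation.

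The other lists were not called (camera adjusted p from 0.0735 to 0.995), with 0 members called over all genes and, outside the TGF-beta and residency list, 0 adjusted over the list alone. Their median log2 fold changes were -0.05 for interferon-stimulated genes, -0.04 for TGF-beta and residency genes, -0.11 for cell cycle (Ccne1 nearest), -0.05 for glycolysis and hypoxia (Ankrd37 nearest), -0.04 for oxidative phosphorylation (Cox5b nearest) and -0.05 for cytosolic ribosomal proteins (Rpl7 nearest). They were -0.17 for endotoxin-responsive myeloid genes (Cxcl1 nearest), 0.06 for enterocyte markers (Mttp nearest), -0.60 for goblet, Paneth, tuft and endocrine markers (Tff3 nearest), -0.11 for macrophage and dendritic cell markers (Xcr1 nearest) and 0.09 for neutrophil, mast cell and eosinophil markers (Kit nearest). The last of these had a positive median and mean while camera gave the direction as lower, at an adjusted p of 0.995. Cytosolic ribosomal proteins (0.0735) were called lower in 8 of 23 alternatives, which were the replicate block (0.0118), the naming covariate (0.00803), the effective-length offset (0.0340), and leaving out osteopontin library 1 (0.00298), osteopontin library 2 (0.00801), null library A (6.33e-04), null library B (2.65e-04) or null libraries 1 and A together (0.0163). With an estimated correlation over all 8 libraries their adjusted p = 0.761. Leaving out 1 library also gave lower calls for interferon-stimulated genes (osteopontin A, 0.00573), cell cycle (osteopontin A, 0.0396, or null 1, 0.0339), glycolysis and hypoxia (osteopontin 1, 0.0210), endotoxin-responsive genes (null 2, 0.0398) and macrophage and dendritic cell markers (osteopontin 1, 0.0197, or null B, 0.00934). Interferon-stimulated genes were also called lower with voom (0.0219), endotoxin-responsive genes with no filter (0.0124), and TGF-beta and residency genes (0.0224), oxidative phosphorylation (0.0349) and glycolysis and hypoxia (0.0454) without null libraries 1 and A. With an estimated correlation over all 8 libraries the adjusted p was 0.617 for the interferon, cell cycle and glycolysis lists, 0.563 for the endotoxin and TGF-beta lists, and 0.761 for the macrophage and oxidative phosphorylation lists. Without both B libraries edgeR called Cxcl1 lower (adjusted p = 0.00330). Cxcl1 stood at 5.73 and 4.44 CPM in null libraries 1 and A, which had the highest fibroblast sums. It stood at 0.440 and 0.184 CPM in null libraries 2 and B. In osteopontin libraries 1, 2 and A it lay at 0.0147 to 0.0281 CPM, under the counting floor, and in osteopontin library B at 0.630 CPM. The call therefore does not show a lower endotoxin-type response of the lymphocytes.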

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

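All tests of explanations in this part were chosen after the result was seen, except the test for a mislabelled library. Among 150 groups of 4 libraries, 24 had 1 library far from the other 3. Chance alone would set 1 library apart in about 1 in 20 groups of independent measures, or 7.5 here. That number is only a rough guide, because the marker sums were put together after the data were seen and some measures share reads. Osteopontin library B was the library set apart 9 times and null library B 10 times. The first principal component (27.4% of the variance) also set these 2 apart from the other 6 libraries.

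In the osteopontin group, library B was highest for fibroblast (24.3 CPM), endothelial (35.7 CPM), enterocyte (55.3 CPM) and inducible stress (129.6 CPM) transcript sums, for mitochondrial ribosomal RNA (2796 CPM) and ribosomal RNA share (0.280%), and for Cxcl1 (0.630 CPM) and Pdgfra (0.264 CPM), and lowest for Bcl2 (55.0 CPM). Library 2 was highest for Tnfrsf18 (35.2 CPM), Cox5b (69.4 CPM) and Ptprc (2172 CPM) and lowest for Nid1 (3.03 CPM). Library 1 was lowest for gamma-delta receptor transcripts (809.7 CPM). In the null group, library B was highest for enterocyte transcripts (63.3 CPM), Tff3 (11.1 CPM), Eloa (113.1 CPM), Bcl6 (82.9 CPM), Ccne1 (9.57 CPM), Sqle (37.4 CPM), Mcl1 (516.7 CPM), mitochondrial ribosomal RNA (1990 CPM) and ribosomal RNA share (0.199%), and lowest for genes with at least 1 read (20225). The ribosomal RNA share counts mitochondrial ribosomal RNA, which made up nearly all of it in both B libraries, so these are not separate traits.

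The 35 genes lower when osteopontin library B was left out included Fos, Hspa1a, Col4a1, Igfbp7, Sparcl1 and Tek. A candidate explanation is RNA from endothelial or other stromal cells, which the CD45 sort should have removed: over 10 endothelial genes outside the marker sums and the called genes, the level in library B was a median of 13.2 times the highest of the other osteopontin libraries and higher in 9 of 10 (Flt1 12.6 CPM, Tie1 10.5 CPM, but Calcrl lower at 7.68 CPM), which shows such RNA in that library but not that it carried the stress transcripts. A mislabelled library cannot be told apart from a correct label: over the 100 leading genes of a fit without it, library B lay at a median position of 0.445 between the osteopontin (0) and null (1) means, within the ranges of the held-out null libraries (0.388 to 0.703) and of the other 3 osteopontin libraries (0.406 to 0.694). The test did not specify beforehand how position is measured, and a least-squares projection put library B at 0.985, above every other library held out the same way (0.240 to 0.760). That projection gives most weight to genes with the largest group difference, such as Fos, Hspa1a and Col4a1. Its value thus partly restates the high levels of these genes in library B and is not separate evidence of a wrong label. An effect of osteopontin on the stress genes stays open too, because stromal transcripts differed between the same libraries. The sum of the stress genes, put together after the data were seen, gave an exact permutation p = 0.0571 (two-sided, adjusted p = 0.324).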

How the results depend on the processing

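The alternatives that left out both B libraries, or null libraries 1 and A, were chosen after seeing the data. The count of 0 genes higher and 0 lower held for the covariate, other scalings, strict filter, effective-length offset, protein-coding genes, thresholds of 0.01 and 0.10 and the test against a 1.5-fold change. DESeq2 gave 21 higher and 59 lower, voom 1 lower, no filter 3 higher and 1 lower, and leaving out both B libraries 1 higher and 48 lower. Leaving out single libraries gave 0 to 2 higher and 0 to 35 lower, and 4 to 10 lists. Of the 30 lists, 7 of which were called at first, 0 were called with an estimated correlation, 1 with fry, 0 with fry and the replicate block, 4 without both B libraries and 11 without null libraries 1 and A. Of 1182 values of named genes under alternatives, 1160 kept their sign and side of the threshold, 15 were newly called, and 7 turned sign with no call. These were Il2ra (0.015 with the effective-length offset, -0.30 to 0.18 over single libraries left out, positive without osteopontin library 1 or 2 or null library A, and 0.26 without null libraries 1 and A), Itgb3 (0.056) and Bcl2l11 (-0.024), both without null libraries 1 and A. DESeq2 gave 10 of the 15 new calls, 2 were Ubn2 without a filter (adjusted p = 0.0121) and without osteopontin library B (0.0460), and 3 were Nid1 (0.0140), Pdgfra (0.00724) and Cxcl1 (0.00330), called lower by edgeR without both B libraries. The cause was not tested.

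The labels do not say that a replicate name marks a shared animal or day. Same-named libraries deviated together with correlations of 0.0437 to 0.123, only 1 of 4 above 0.1, so the names were not taken to pair the libraries, although 7 of 8 libraries correlated best with their own name and the real naming gave the highest mean of the 24 pairings (exact permutation p = 0.0417, one-sided, the smallest they can give). The fit with the replicate block called 0 genes higher and 0 lower with edgeR (997 at an unadjusted p under 0.05), and 8 lists. The permutation tests and splits of 4 against 4 libraries ignored the names, so they do not allow for sharing between same-named libraries.

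At this depth and spread, 38.8% of simulated 1.5-fold changes were called, so a change of that size would often be missed. The simulated genes were drawn independently, without the differences between libraries that many real genes share. Recovery in the real comparison may therefore differ from this rate. With 0 genes called, each of the 35 splits of the 8 libraries into 4 and 4 must give as many, so the splits decide nothing about genes; the highest of the others called 3 on 1 side. For lists, 12 of the 35 splits called at least 7, up to 10, so chance is not excluded for the preset-correlation calls.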

Other observations

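The tests of a shared pool, of carried-over reads and of the B libraries were chosen after the result was seen, and the criterion for the last was changed after its median was known. Fcgbp, a goblet cell mucus protein gene, stood at 59.2 CPM in null library B and at 1.47 CPM or less in the other 7. The Y-linked genes Ddx3y, Eif2s3y and Uty summed to 0.395 ± 0.309 CPM with osteopontin and 1.29 ± 0.260 CPM without (exact permutation p = 0.0286, the smallest that 4 against 4 allows, adjusted p = 0.324), and all 4 null libraries lay above all 4 osteopontin libraries. This Y-linked sum was a trace in every library, from 0.0541 CPM in osteopontin library A, near the counting floor, to 1.52 CPM in null library A. Xist stood at 1051 ± 98.8 and 923.0 ± 119.6 CPM (exact permutation p = 0.171, adjusted p = 0.673), and at 802.0 CPM or more in every library. The Y-linked difference therefore does not show a difference in sex between the groups.

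Mitochondrially encoded coding transcripts were fitted lower with osteopontin by a median log2 change of -0.40. Their share of reads was lower with osteopontin in all 4 same-named pairs. Chance is not excluded: 2 of the 35 splits gave a median as large in size (0.40 for the real one, 0.47 for the other, which put both libraries named 1 on the same side). The B libraries hold the extreme values, and without both the median was -0.23 with 12 of 13 members lower (adjusted p = 3.80e-08 with the preset and 0.775 with an estimated correlation), so whether these libraries alone are the cause cannot be told apart from a smaller difference in the rest. The median passed a first bound of -0.2 against that cause, but by less than its standard error of 0.14 between the 6 libraries, and the differences of the 3 same-named pairs, all lower, averaged -0.20 (SE 0.045), which is not past that bound by its error either. The list holds coding genes only, and the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 went the other way. They summed to 1489 ± 871.3 CPM with osteopontin and 1203 ± 525.1 without (exact permutation p = 0.457, two-sided, adjusted p = 0.673). This sum was higher with osteopontin in all 4 same-named pairs, so mitochondrial transcripts as a whole were not lower. An effect of osteopontin on the coding transcripts stays open.

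The immunoglobulin A transcript Igha stood at 2591 and 3132 CPM in the osteopontin and null libraries named 1, 4793 and 4684 in those named 2, 5855 and 6612 in those named A, and 2722 and 1876 in those named B. Across 86 immunoglobulin variable segments, which are not independent replicates, deviations from the group means correlated by 0.296 on average for same-named libraries and by -0.0981 for differently named ones, all 4 same-named values lay above 0.1 (0.156 to 0.466), and the real naming gave the highest mean of the 24 pairings (exact permutation p = 0.0417, one-sided), in the segments in which the sharing was first seen. A hypothesis is that same-named libraries came from one pool of cells, which cannot be told apart from other reasons for sharing: across 93 T cell receptor variable segments the same-named mean was 0.165 against -0.0552, and 3 of the 24 pairings were as large (exact permutation p = 0.125, one-sided). Reads carried over between same-named libraries stay open too, as does a shared day of preparation, which was not tested: fibroblast transcripts differed 38.9-fold and 20.5-fold within the pairs named 1 and A, but 1.49-fold and 3.87-fold within those named 2 and B. The largest share of the partner's reads that genes other than antigen receptors allowed was then taken out (0.678% to 39.0%, the 10th lowest limit per library). With it removed, the mean same-named correlation on log2(CPM + 1) went from 0.326 to 0.184, still the highest of the 24 pairings. In the pair named A the limits were 0.800% and 3.04%, and its correlation went from 0.296 to 0.222. In the pair named B they were 0.678% and 0.902%, and its correlation went from 0.336 to 0.272. Carried-over reads up to these limits thus do not account for the correlation left in these pairs. The correlation of the pair named 2 went from 0.508 to 0.307, and that of the pair named 1 from 0.161 to -0.0659. The 39.0% was taken out of null library 1 in the pair named 1 and is an upper limit, not an estimate. Removing so much of a partner can by itself lower the correlation, so the fall in the pair named 1 does not show carried-over reads.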
